A study of Mus musculus with 4 samples.

How the data were processed

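RNA-seq was done on whole small intestine of mice at postnatal day 8. The series holds 4 samples in 2 groups. The control group has 2 samples, per the design text from mice with floxed Lats1 and Lats2 and no Cre. The genotype label of these samples instead gives both genes as deleted, without Cre, and the design text was followed. The Lats1/2 KO group has 2 samples from mice labelled as Lats1/2 knockouts with Villin-Cre, which is active in the intestinal epithelium. Per the labels' protocols, total RNA was extracted with Trizol and a column kit from tissue rinsed in cold buffer, and libraries followed a standard Illumina protocol. No cell type was sorted, so each library mixes epithelium with muscle, connective tissue, nerve, vessel and blood cells.

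Per the submitters' processing notes, the tools STAR, featureCounts and DESeq2 and the build GRCm38 were used. Their versions, roles and order, the strand setting and the treatment of reads that match several places are not given in the sources used here. The deposited table held 29011 Ensembl mouse genes. Its per-library columns held normalized counts, a signal the authors made by dividing gene counts by 1 factor per library, per the file headers and the values. Every value in a column was a whole multiple of the smallest one. Dividing by that step gave whole reads for 100% of the values in each library, within a tolerance of 0.001 reads. The same deposited table gave a log2 fold change, the fold change as a linear ratio, and an adjusted p-value per gene, which the authors computed for mutant over wild type. The authors' log2 fold changes were shrunken toward 0, as their values showed for genes with few reads and for some with many reads whose libraries differed.

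The column names gave the group of each library but not which sample of the group it was. Libraries were therefore numbered within a group in column order, as names only, and no library was paired with another. The recovered depth was 25135964 to 27811313 reads in the control libraries and 30517967 to 32361940 in the Lats1/2 KO libraries. With tested genes split by level into 5 groups of equal size, the median SE of the log2 change was 0.35 in the lowest group and 0.07 in the highest. Genes below the filter were not tested. The labels speak of mice but do not say that each sample came from its own animal. The p-values measure the spread between these samples, and with 2 samples per group that spread was estimated with 2 residual degrees of freedom plus 3.53 prior degrees of freedom from all genes.

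The test fitted was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(normalized count + 1), for 16415 genes with a value of at least 10 in at least 2 libraries. The plan named edgeR for raw counts and this limma fit for size-factor-normalized values, which is what the deposited table held. Fold changes are on the log2(value + 1) scale and understate the change of genes with low values. Adjusted p-values followed Benjamini and Hochberg with a threshold of 0.05. Values of 2 libraries are given as mean ± SD, n = 2 per group.

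Before the data were examined, 11 lists of genes expected in this tissue and pathway, and 21 lists of other pathways, cell types and organs, were fixed. Of their 571 entries, 548 had a row and 488 were tested. There were 8 tested genes in more than 1 list. Each list was described by the number of members past the threshold over all genes and adjusted over the list alone. It was then tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists, with the estimated correlation and fry beside it. Camera called 18 lists, namely 9 of the first 11 and 9 of the other 21. With an estimated correlation 0 lists were called. Fry, which asks whether a list moves one way without comparing it with other genes, called 13. With an estimated correlation camera has only the 2 residual degrees of freedom, so it could hardly call any list. Its smallest unadjusted p was then 0.0559, and the Wnt list, with an estimated correlation of -0.04, also lost its call. That lack of calls therefore decides nothing about the calls at 0.01. Estimated correlations were 0.41 for the goblet, 0.36 for the enteroendocrine and 0.30 for the cell cycle list, and -0.07 for the tuft list. Where the true correlation lies above 0.01, the camera p at 0.01 is too small. Fry gave the 9 called lists of the first 11 adjusted p of 0.0271 to 0.0417.

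The rule for naming genes was also fixed then. It took Lats1, Lats2, Yap1 and Wwtr1, and the 6 largest rises and 6 largest falls past the threshold among genes at or above the median expression of tested genes (a mean of 413 normalized counts) whose groups did not overlap. It added up to 3 members of each of the 11 lists and up to 2 of each of the 21 lists with the smallest adjusted p, and skipped unnamed gene models. It gave 85 genes, some of which are not reported here. Genes outside this rule were chosen after their values were seen and are marked where they appear, except those that stand only as members of a list or family. Positions are 1-based, from the GENCODE annotation of GRCm38, which held 28959 of the 29011 gene IDs.

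The scripts were tested on simulated data for Lats1/2 KO against control, with 200 changed genes. These were drawn only above a set mean count, which left out all genes at the level of the lowest of the 5 groups. The limma fit found 22.4% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 95.5% of those changed 4-fold among 16119 genes. It made 25 false calls, 16.1% of its calls, which is above the nominal 5%. In the data 4508 genes passed, against 200 changed in the simulation. The cut on unadjusted p therefore differs, and neither the found nor the false share carries over. Of 100 unchanged lists, camera gave 2 an unadjusted p under 0.05. The simulated genes were drawn independently, so this does not test camera on lists of correlated genes. The real lists had estimated correlations of up to 0.93 (exocrine pancreas).

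The alternatives were edgeR 4.0.16 on the recovered reads with 3 scalings, DESeq2 1.42.0, limma-voom, no filter, a stricter filter of 1 CPM in 2 libraries, a pseudocount of 0.1, stricter thresholds, and each library left out in turn. Leaving out a library leaves 1 in its group, which is then assumed to vary like the other group. A result given without either library of a group is that of 2 fits, each with 1 of them left out. Refitting limma with 2 other scalings was added after seeing the data. The closing section gives their effect. Groups of 2 are too small for a test of outlying libraries or for a count of other splits of the samples.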

Results

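The 4 libraries profiled the small intestine of mouse pups at postnatal day 8. The 2 control libraries came, per the design text, from mice carrying floxed Lats1 and Lats2 without Cre, while their genotype label gives both genes as deleted and Cre as absent. The 2 Lats1/2 KO libraries came from mice labelled as Lats1/2 knockouts with Villin-Cre, which is active in the intestinal epithelium. Lats1 and Lats2 are the kinases of the Hippo pathway that phosphorylate and restrain the transcriptional co-activators YAP and TAZ. The comparison asks how gene expression in the neonatal small intestine differs between these groups. Recovered depth was 27811313 and 25135964 reads in control replicates 1 and 2, and 30517967 and 32361940 reads in Lats1/2 KO replicates 1 and 2. Between 24119 and 24593 genes had a read in a library. The 10 most abundant genes took 9.31% to 11.1% of each library. Across tested genes, which are not independent replicates, log2 values correlated at r = 0.988 between the control libraries and 0.990 between the Lats1/2 KO libraries. Between the groups r was 0.958 to 0.960. Libraries of 1 group differed by more than the sampling noise of read counts, with a chi-square per degree of freedom of 23.3 for the controls and 15.2 for the knockouts. They were treated as separate samples, as labelled, though this spread does not show whether they came from separate animals.

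Lats1 fell in the Lats1/2 KO samples and Lats2 did not. Lats1 (ENSMUSG00000040021, chromosome 10, 7681214 to 7716460, plus strand of GRCm38) went from 2438 ± 173 (SD, n = 2) normalized counts to 706 ± 64.2 (SD, n = 2). Its log2 change was -1.79 ± 0.10 (SE), a 3.45-fold fall, with an adjusted p of 0.00055 by limma. Lats1 was 2316 and 2560 in the control libraries and 751 and 661 in the knockouts, so each library had the level of its label. Lats2 (ENSMUSG00000021959, chromosome 14, 57689662 to 57758388, minus strand) was 280 ± 9.63 and 275 ± 29.2 (SD, n = 2 each), a log2 change of -0.03 with a 95% interval of -0.34 to 0.28 and an adjusted p of 0.868. The counts cover whole genes, and reads over the deleted part alone were not analysed here, so the Lats2 total does not test its label. Yap1 had a log2 change of 0.04 (adjusted p = 0.652). Wwtr1, which encodes TAZ, had a log2 change of 0.22 (adjusted p = 0.125).

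Of 16415 tested genes, 2491 were higher and 2017 lower in the Lats1/2 KO samples, together 27.5% of them. At least a 2-fold change was seen in 694 of the higher and 736 of the lower genes. The 6 largest rises among the more abundant genes were Pla1a, Bmp8b, BC067074, Gcnt1, Lrp2 and Cldn8. Pla1a, a phospholipase acting on phosphatidylserine (chromosome 16, 38396117 to 38433145), rose from 31.3 ± 10.6 to 2928 ± 387 normalized counts (SD, n = 2 each), 92.7-fold (log2 change 6.54 ± 0.24 SE). Bmp8b, a bone morphogenetic protein, rose 57.4-fold, from 10.4 and 26.3 normalized counts in the control libraries to 929 and 1095 in the knockouts. BC067074 rose 35.3-fold, and Gcnt1, a glycosyltransferase that branches O-linked sugars, 28.7-fold. Lrp2, the endocytic receptor megalin (chromosome 2, 69424340 to 69586065), rose 24.1-fold from 198 ± 10.8 to 4801 ± 178 (SD, n = 2 each) and had the smallest adjusted p of these genes, 0.000105. Cldn8, a tight junction claudin, rose 21.2-fold, from 23.8 and 65.1 normalized counts in the control libraries to 859 and 858 in the knockouts. The 6 largest falls were Gkn3, C8b, Olfm4, Spink4, Itln1 and Cyp3a25. Olfm4, a secreted protein of the crypt base (chromosome 14, 79984081 to 80023139), fell 40.1-fold from 17042 ± 2110 to 432 ± 127 (SD, n = 2 each; log2 change -5.32 ± 0.21 SE). C8b, a complement component, fell 41.0-fold and Cyp3a25, a cytochrome P450, 13.6-fold. Gkn3, a gastrokine of the stomach, fell 81.2-fold, with 2544 and 1064 normalized counts in the control libraries and 7.40 and 47.9 in the knockouts. By limma, 6776 genes had an unadjusted p under 0.05, and the groups did not overlap in 68.3% of tested genes, against 33.3% by chance. The 4508 calls became 1894 without Lats1/2 KO replicate 1 and 1869 without Lats1/2 KO replicate 2.

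**Figure D1:**
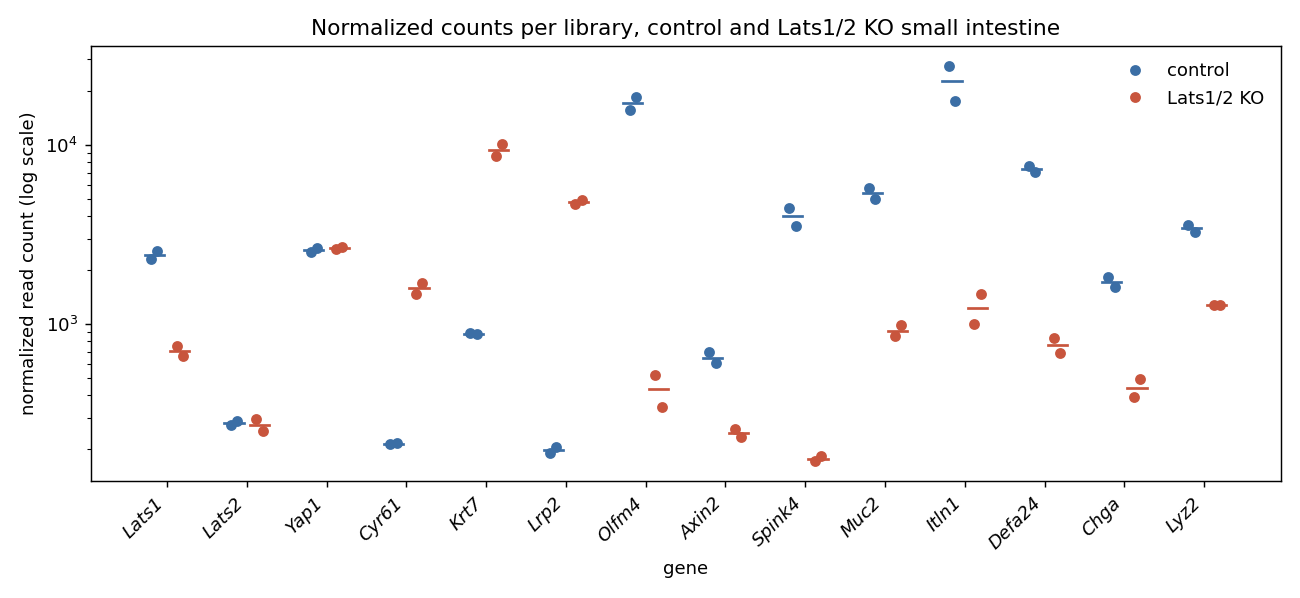
Normalized read count (log axis) of 14 genes in each library, with 2 control points and 2 Lats1/2 KO points per gene and a bar at each group mean. Lats1, Olfm4, Axin2, Spink4, Muc2, Itln1, Defa24, Chga and Lyz2 lie lower in both knockout libraries, Cyr61, Krt7 and Lrp2 lie higher, and the groups overlap for Lats2 and Yap1.

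Targets of YAP, TAZ and their TEAD partners were mostly higher in the Lats1/2 KO samples. Of 26 tested members 14 rose, 3 fell and 9 did not pass (15 and 5 adjusted over the list alone), with a median log2 change of 0.59. Cyr61, a secreted matricellular protein and classic YAP target (ENSMUSG00000028195, chromosome 3, 145646976 to 145649981), rose 7.31-fold from 215 ± 2.78 to 1583 ± 150 normalized counts (SD, n = 2 each). Myof, a membrane repair protein, rose 3.81-fold, and Ajuba, a LIM domain protein that binds the LATS kinases, 2.81-fold. Further members chosen after their values were seen were Ctgf, F3 and Amotl2, which rose 4.64-fold, 4.53-fold and 4.16-fold. Ankrd1, chosen in the same way, also rose, from 2 and 0 reads in the control libraries to 27 and 31 in the knockouts. The 3 members that fell, also named after their values were seen, were Axl (log2 change -0.68), a receptor tyrosine kinase, Gadd45a (-0.70), a stress response gene, and Igfbp3 (-0.48), which binds insulin-like growth factors. Camera gave the list an adjusted p of 0.00164, and 0.425 with an estimated correlation. The list had 9 members that rose and 1 that fell without Lats1/2 KO replicate 2.

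Among 24 components of the Hippo pathway itself, 8 rose, 1 fell and 15 did not pass (8 and 2 adjusted over the list alone), with a median log2 change of 0.16. Wwc2, a scaffold that activates the LATS kinases, rose 4.41-fold from 1199 ± 60.1 to 5284 ± 234 normalized counts (SD, n = 2 each). Lats1 was the 1 member that fell. Vgll3, Wwc1, Amot and Tead1, chosen after their values were seen, rose 6.16-fold, 2.59-fold, 2.01-fold and 1.49-fold. Vgll3 and Tead1 encode a TEAD cofactor and a TEAD factor, and Amot an inhibitor of YAP. The list had an adjusted p of 0.0241 by camera and 0.425 with an estimated correlation. Without either Lats1/2 KO library and with no filter 5 members rose, and 2 fell with the stricter filter and with limma scaled by library size. The lists share Tead1, Wwc1, Amotl1 and Amotl2 with the YAP, TAZ and TEAD targets.

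Genes of the fetal and regenerating intestinal epithelium were mostly higher. Of 23 tested, 15 rose, 1 fell and 7 did not pass (16 and 1 adjusted over the list alone), with a median log2 change of 1.64. Krt7, a keratin of simple ductal epithelia (chromosome 15, 101411043 to 101430313), rose 10.6-fold from 885 ± 6.41 to 9378 ± 983 normalized counts (SD, n = 2 each). Krt23, another keratin, rose 4.31-fold. Clu, Anxa1 and Il33, chosen after their values were seen, rose 6.63-fold, 6.53-fold and 6.70-fold. Itga2, an integrin chain named after its value was seen, was the 1 member that fell (log2 change -0.59), and 2 fell without control replicate 1. Ly6a, a surface antigen used to mark regenerating epithelium and also chosen after its values were seen, had a log2 change of 0.37 and an adjusted p of 0.082. Camera gave an adjusted p of 2.88e-06, and 0.425 with an estimated correlation.

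**Figure D2:**
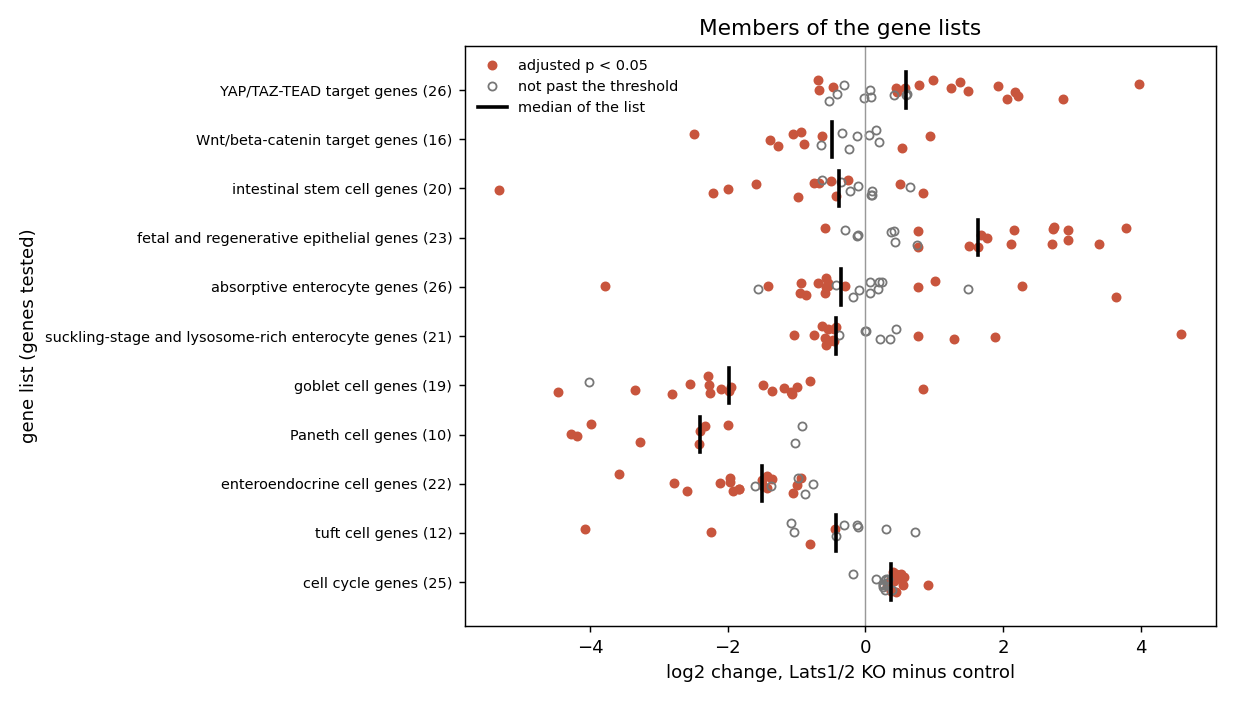
Log2 change (Lats1/2 KO minus control) of each tested member of 11 gene lists, with filled points past an adjusted p of 0.05, open points not past it, and a bar at the list median. Medians lie at 1.64 for the fetal and regenerative list and at -1.99, -2.41 and -1.50 for the goblet, Paneth and enteroendocrine lists.

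Goblet cell genes fell nearly throughout. Of 19 tested members 17 fell, 1 rose and 1 did not pass, and the counts were equal adjusted over the list alone. Muc2, the main gel-forming mucin (chromosome 7, 141690340 to 141754693), fell 5.83-fold from 5362 ± 499 to 919 ± 91.3 normalized counts (SD, n = 2 each). Spink4, a secreted peptidase inhibitor, fell 22.2-fold and Ccl6, a chemokine, 10.2-fold. Atoh1 and Spdef, transcription factors of secretory and goblet cell fate chosen after their values were seen, fell 3.86-fold and 4.84-fold. Klf4, the 1 member that rose, and Retnlb, the 1 that did not pass, were also named after their values were seen. Klf4 increased 1.78-fold, and Retnlb had a log2 change of -4.02 ± 2.54 (SE). The list median was -1.99, with an adjusted p of 1.14e-09 by camera and 0.425 with an estimated correlation.

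Paneth cell genes fell as well, 8 of 10 tested with 0 rising and 2 not past the threshold (9 fell adjusted over the list alone). Itln1, a lectin that binds microbial sugars, fell 18.2-fold from 22553 ± 7152 to 1229 ± 331 normalized counts (SD, n = 2 each). The defensins Defa24 and Defa30, antimicrobial peptides, fell 9.67-fold and 19.4-fold. Defensin genes have near-identical copies that can share reads, so the value of a single defensin is uncertain. Lyz1, the Paneth cell lysozyme chosen after its values were seen, fell 3.98-fold. The list median was -2.41. Camera gave an adjusted p of 1.52e-07, and 0.425 with an estimated correlation.

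Enteroendocrine cell genes fell in 17 of 22 tested members, with 0 rising and 5 not past the threshold (21 fell adjusted over the list alone). Chgb and Chga, granule proteins of hormone-secreting cells, fell 3.78-fold and 3.92-fold. Chga went from 1723 ± 160 to 441 ± 71.5 normalized counts (SD, n = 2 each). Cck, the hormone cholecystokinin, fell 4.32-fold. Neurog3, the transcription factor of endocrine progenitors chosen after its values were seen, fell 12-fold from 48.9 ± 0.352 to 3.20 ± 0.593 (SD, n = 2 each). The median was -1.50, with an adjusted p of 5.14e-10 by camera and 0.425 with an estimated correlation. Tuft cell genes fell in 4 of 12 tested members and rose in 0, and 8 did not pass (4 fell adjusted over the list alone). Sucnr1, the succinate receptor of tuft cells, fell 16.9-fold from 682 ± 241 to 38.4 ± 5.82 (SD, n = 2 each). Ltc4s, which makes leukotriene C4, fell 4.75-fold. Dclk1, a common tuft cell marker chosen after its values were seen, had a log2 change of -0.32 and an adjusted p of 0.200. The tuft list had a median of -0.43, an adjusted p of 0.0329 by camera and 0.425 with an estimated correlation. Without either Lats1/2 KO library 2 of its members fell.

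Intestinal stem cell genes were lower on balance, with 10 of 20 tested falling, 2 rising and 8 not past the threshold (11 and 2 adjusted over the list alone). Beside Olfm4, Slc12a2, an ion cotransporter of crypt cells, fell 1.98-fold from 4639 ± 121 to 2347 ± 83.8 normalized counts (SD, n = 2 each), and Aqp4, a water channel, 4.62-fold. Lgr5, the receptor that marks crypt base stem cells and was chosen after its values were seen, fell 3.01-fold from 327 ± 3.22 to 108 ± 12.8 (SD, n = 2 each). Cdk6, a cell cycle kinase, and Soat1, an enzyme of cholesterol ester synthesis, were the 2 members that rose (log2 changes 0.84 and 0.51) and were named after their values were seen. The median was -0.39, with an adjusted p of 0.00288 by camera and 0.485 with an estimated correlation. Without either Lats1/2 KO library 0 members rose, and without Lats1/2 KO replicate 2 the number that fell was 5.

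Targets of Wnt and beta-catenin, the pathway that maintains crypts, fell in 7 of 16 tested members, rose in 2 and did not pass in 7, with equal counts adjusted over the list alone. Apcdd1, an inhibitor of Wnt signalling, fell 5.64-fold, and Axin2, a feedback inhibitor, 2.62-fold from 651 ± 63.5 to 247 ± 17.7 normalized counts (SD, n = 2 each). Cd44, a hyaluronan receptor of crypt cells, fell 2.40-fold. Ccnd1, which encodes cyclin D1, and Tcf7, a transcription factor of the pathway, were the 2 that rose (log2 changes 0.93 and 0.53) and were named after their values were seen. The median was -0.49. Camera gave an adjusted p of 0.0359, and 0.425 with an estimated correlation. The call was lost without Lats1/2 KO replicate 2 (adjusted p = 0.0591), and 1 member rose in each fit without 1 library and with no filter.

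Genes of absorptive enterocytes moved in both directions. Of 26 tested, 12 fell, 4 rose and 10 did not pass (13 and 5 adjusted over the list alone), with a median of -0.36 and an adjusted p of 0.0663 by camera. Slc2a5, the fructose transporter, fell 1.92-fold from 1192 ± 53.2 to 619 ± 20.7 normalized counts (SD, n = 2 each). Xpnpep2, a brush border aminopeptidase, rose 4.84-fold from 674 ± 58.8 to 3262 ± 177 (SD, n = 2 each), and Mgam, a disaccharidase, 2.02-fold. Treh, Sis and Enpep were chosen after their values were seen. Treh, the trehalose-digesting enzyme, fell 13.8-fold and Sis, sucrase-isomaltase, 2.66-fold, while Enpep, a brush border peptidase, rose 12.5-fold. The camera call was gained with limma-voom (adjusted p = 0.0348) and with no filter (0.0132), and fry, which does not compare a list with other genes, gave an adjusted p of 0.0271. Without Lats1/2 KO replicate 1, 5 members fell, and without replicate 2, 7 fell.

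The suckling-stage and lysosome-rich enterocyte list also split. Of 21 tested genes 11 fell, 4 rose and 6 did not pass (12 and 5 adjusted over the list alone). Among the members that rose were Lrp2 and Cubn (the endocytic receptor cubilin, 2.43-fold, from 9228 ± 348 to 22416 ± 262 normalized counts, SD, n = 2 each) by the rule and Dab2, an endocytic adaptor chosen after its values were seen, 3.70-fold. The list median was -0.43 and its mean 0.13, and camera gave an adjusted p of 0.154. With edgeR scaled by library size alone the direction of the test turned (adjusted p = 0.676), as it did with fry (0.215). Members that fell numbered 3 without Lats1/2 KO replicate 1 and 5 without replicate 2.

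Cell cycle genes were slightly higher. Of 25 tested, 14 rose, 0 fell and 11 did not pass (19 rose and 1 fell adjusted over the list alone), with a median log2 change of 0.38. Cdc20, an activator of the anaphase-promoting complex, rose 1.89-fold from 750 ± 82.7 to 1412 ± 77.3 normalized counts (SD, n = 2 each). Kif20a, a mitotic kinesin, rose 1.46-fold and Bub1b, a spindle checkpoint kinase, 1.43-fold. Camera gave an adjusted p of 1.84e-06, and 0.446 with an estimated correlation. Without Lats1/2 KO replicate 1, 1 member rose, and without replicate 2, 4 rose. Kif20a and Bub1b lost their calls without either knockout library (adjusted p 0.0603 to 0.0753). Of 15 p53 targets, 3 rose, 1 fell and 11 did not pass, with a median of 0.18 and an adjusted p of 0.193. Cdkn1a, the cell cycle inhibitor p21, rose 2.30-fold and Aen, an apoptosis-enhancing nuclease, 1.45-fold. The counts adjusted over the list alone were also 3 and 1, Aen lost its call without either knockout library (adjusted p 0.064 to 0.0784), and 1 member rose there. None fell without Lats1/2 KO replicate 1 or with no filter, and 2 fell without replicate 2.

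Medians of the other signalling lists lay between -0.27 and 0.44. In the Notch list of 13 tested genes, 2 rose, 3 fell and 8 did not pass, as also adjusted over the list alone (median -0.27, adjusted p = 0.101, and 0.0464 with no filter). Its ligand Jag2 rose 2.54-fold, and Nrarp, a feedback inhibitor of Notch signalling, fell 3.35-fold. Only 1 Notch member rose without either knockout library, without control replicate 2 and with no filter. Of 19 hedgehog and BMP genes, 6 rose, 1 fell and 12 did not pass (8 and 3 adjusted over the list alone; median 0.18, adjusted p = 0.209). Id2 and Id3, transcriptional inhibitors induced by BMP, rose 2.00-fold and 1.59-fold. In that list 2 members rose without Lats1/2 KO replicate 1. The number that fell was 0 without either knockout library or control replicate 2 and with no filter. It was 2 without control replicate 1, with the stricter filter and with edgeR scaled by TMM or DESeq2 size factors. Interferon response genes rose in 5 of 19 and fell in 0 (9 and 1 adjusted over the list alone; median 0.44). Bst2, an antiviral membrane protein, rose 3.22-fold and Mx1, an antiviral GTPase, 2.80-fold. The interferon list had an adjusted p of 0.0241 by camera, 0.485 with an estimated correlation and 0.0853 by fry. The camera call was lost without Lats1/2 KO replicate 2 (adjusted p = 0.0566), and the number that rose was 11 without control replicate 2, where 2 fell, and 2 without either knockout library and with no filter. Of 16 inflammatory cytokine genes 0 rose, 2 fell and 14 did not pass, as also adjusted over the list alone (median -0.15, adjusted p = 0.359). These were the chemokine Ccl3, which fell 3.95-fold, and the cytokine Il1a, 2.46-fold, which lost its call without Lats1/2 KO replicate 1 (adjusted p = 0.0642), where 1 fell. Without control replicate 1, 2 cytokine genes rose, and without control replicate 2, 4 fell. Their summed normalized counts were 61002 and 2224 in the control libraries and 13021 and 5501 in the knockouts. Immediate early genes rose in 3 of 15 and fell in 0 (1 and 0 adjusted over the list alone; median 0.33, adjusted p = 0.0697, and 0.0122 without control replicate 2, where 8 rose and 1 fell, and 0.024 with no filter). Without either knockout library and with no filter 1 immediate early gene rose. Fos rose 3.37-fold. Dusp1, a phosphatase, rose 1.77-fold and lost its call without either knockout library (adjusted p 0.123 to 0.145) and with no filter (0.0781).

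Of 63 tested markers of fibroblasts, vessels, nerve and smooth muscle, 56 had a negative log2 change, but only 12 fell past the threshold and 0 rose. Fibroblast and matrix genes fell in 7 of 20 and rose in 0 (10 fell adjusted over the list alone; median -0.29). Pdgfra, a growth factor receptor of fibroblasts, fell 1.46-fold and Tnc, tenascin C, 1.60-fold. Camera gave an adjusted p of 0.00164, and 0.425 with an estimated correlation. The number that fell was 4 with no filter, 1 without Lats1/2 KO replicate 1, where Tnc had an adjusted p of 0.0645, and 0 without replicate 2, where Pdgfra had an adjusted p of 0.0561 and Tnc of 0.0655. Endothelial genes fell in 3 of 14 and rose in 0, as also adjusted over the list alone (median -0.25; adjusted p = 0.00426 by camera and 0.485 with an estimated correlation). Prox1, a lymphatic endothelial factor that is also in the Wnt list, fell 1.92-fold and Pecam1, an adhesion molecule, 1.40-fold. Both lost their calls without either knockout library (adjusted p 0.0504 to 0.114), and 0 members fell without Lats1/2 KO replicate 2. Enteric neuron and glia genes fell in 2 of 15 and rose in 0, as also adjusted over the list alone (median -0.30; adjusted p = 0.0222 by camera and 0.485 with an estimated correlation). S100b, a calcium-binding protein of glia, fell 6.15-fold from 2138 ± 145 to 350.0 ± 72.4 normalized counts (SD, n = 2 each). Snap25, a synaptic protein, fell 1.67-fold and lost its call without Lats1/2 KO replicate 1 or 2 or control replicate 2 (adjusted p 0.109 to 0.123) and with no filter (0.0573). The camera call of this list was lost without Lats1/2 KO replicate 2 (adjusted p = 0.0933), and 1 member fell without either knockout library and with no filter. None of 14 smooth muscle genes passed, also adjusted over the list alone (median -0.18, adjusted p = 0.0782 by camera). Synpo2 had a log2 change of -0.57 (adjusted p = 0.0538) and Hhip of -0.33 (adjusted p = 0.0762). Synpo2 passed with DESeq2 (adjusted p = 0.0134) and without Lats1/2 KO replicate 1 (0.0305), and Hhip without control replicate 1 (0.021). Lats1/2 KO replicate 2 was the lowest library for this list, and without it the direction of the test turned (adjusted p = 0.961), while without replicate 1 the adjusted p was 0.000171 and 3 genes fell. It was also past the threshold without control replicate 1 (0.0318), where 1 gene fell, and with no filter (0.0404). Fry gave the fibroblast, endothelial and neuron and glia lists adjusted p of 0.0562, 0.0853 and 0.0853.

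Myeloid cell genes fell in 10 of 16 and rose in 0 (12 fell adjusted over the list alone), with a median of -0.78. Lyz2, the lysozyme of macrophages and neutrophils, fell 2.67-fold from 3412 ± 203 to 1275 ± 7.78 normalized counts (SD, n = 2 each), and Adgre1, which encodes the macrophage antigen F4/80, 2.62-fold. Camera gave an adjusted p of 2.21e-06, and 0.425 with an estimated correlation. Without control replicate 1 or Lats1/2 KO replicate 1 the number that fell was 6. Of 11 B and T lymphocyte genes 2 fell and 0 rose, as also adjusted over the list alone. Cd4, a surface receptor of T cells, fell 2.42-fold and Ighm, the constant region of immunoglobulin M, 1.96-fold. The lymphocyte list had a median of 0.54 and a mean of 0.10, while camera put it below other genes, with an adjusted p of 0.984. Of 8 mast cell genes 2 fell and 0 rose, as also adjusted over the list alone (median -0.26, adjusted p = 0.121, and 0.0464 without control replicate 1). These were Kit, a receptor also found on pacemaker cells of the gut wall (1.92-fold), and Hdc, which makes histamine (2.17-fold). Hdc lost its call with DESeq2 (adjusted p = 0.146), with no filter (0.0957) and without any 1 of the 4 libraries (0.0543 to 0.157), and 1 mast cell gene fell in the latter fits and with no filter. None of 7 erythroid genes passed, also adjusted over the list alone (median -0.05, adjusted p = 0.745). Slc4a1, the anion exchanger of red cells, had a log2 change of -0.23 (adjusted p = 0.587).

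Lists of neighbouring organs were tested for other tissue in the samples. None of 16 exocrine pancreas genes passed, also adjusted over the list alone, and their median was -1.05, with an adjusted p of 0.0471 by camera and 0.673 with an estimated correlation. Their summed normalized counts were 42773 and 22114 in the control libraries, 5287 in Lats1/2 KO replicate 1 and 30485 in replicate 2. Without Lats1/2 KO replicate 1 the direction turned and 2 members rose (adjusted p = 0.111), and the call was also lost without control replicate 1 (0.118) and with edgeR (0.123 to 0.138). Without Lats1/2 KO replicate 2 the adjusted p was 1.18e-12 and 15 members fell, and without control replicate 2, 1 fell. By fry it was 0.537. Reg1, a secreted lectin, was 19066 and 4012 in the controls and 1126 and 3202 in the knockouts (log2 change -2.20, adjusted p = 0.102, and 0.0142 without control replicate 2). Cela1, an elastase, had a log2 change of -1.46 (adjusted p = 0.109, and 0.00894 without Lats1/2 KO replicate 2). Of 6 liver genes 3 fell and 1 rose, as also adjusted over the list alone (median -1.46, adjusted p = 0.119, 0.0342 to 0.0356 with edgeR and 0.0419 without control replicate 2), and 2 rose without control replicate 1. Ttr, the thyroxine carrier transthyretin, fell 3.64-fold and Serpina1a, alpha-1-antitrypsin, 5.92-fold. Serpina1a has near-identical copies that can share reads. Of 6 colon genes 4 fell and 1 rose, as also adjusted over the list alone (median -1.44, adjusted p = 0.0439 by camera and 0.425 with an estimated correlation). The camera call was lost without control replicate 1 (adjusted p = 0.0895). Muc4, a membrane mucin, fell 4.53-fold, and Aqp4, also in the stem cell list, fell too. Car4, the 1 member that rose and chosen after its values were seen, went from 0 and 2 reads to 161 and 223. Of 3 stomach and squamous genes 1 fell and 0 rose (1 and 1 adjusted over the list alone). Pgc, the precursor of a gastric protease, fell from 240 and 93 reads to 0 and 7. Atp4a, the proton pump of the stomach, had a log2 change of 1.45 (adjusted p = 0.0813) and passed without control replicate 2 (0.0407), where 1 stomach gene rose. The stomach list had a median of 0.47, a mean of -1.33 and an adjusted p of 0.984. Of 5 adipocyte genes 2 rose and 0 fell (2 and 1 adjusted over the list alone; median 0.34, adjusted p = 0.318). Pparg, a nuclear receptor, rose 2.15-fold and Lipe, a lipase, 1.38-fold. Both lost their calls without either knockout library (adjusted p 0.0565 to 0.138), where 0 members rose. Lipe also lost it without control replicate 2 (0.0574) and with no filter (0.0598), where 1 rose. An adipocyte gene fell without Lats1/2 KO replicate 1 or control replicate 2, with limma-voom and with the stricter filter. None of 6 mitochondrially encoded genes passed (2 fell adjusted over the list alone; median -0.34). The mitochondrial list had an adjusted p of 0.0471 by camera and 0.495 with an estimated correlation, and the camera call was lost with edgeR (0.0885 to 0.127) and without either knockout library (0.0591 to 0.146). By fry the adjusted p was 0.0727. The subunits of respiratory complex I mt-Nd4 and mt-Nd2 had log2 changes of -0.41 (adjusted p = 0.0536) and -0.38 (adjusted p = 0.0541). Both passed with edgeR (adjusted p 0.0195 to 0.0291), limma-voom (0.0194 to 0.0207), DESeq2 (0.000194 to 0.000276) and the stricter filter (0.0481). They also passed in the limma fit scaled by library size (0.0434 to 0.0467), and mt-Nd4 in that scaled by TMM (0.0498). The number of mitochondrial genes that fell was 3 to 4 with edgeR, 4 with limma-voom, 2 with the stricter filter and 1 with no filter.

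**Figure D3:**
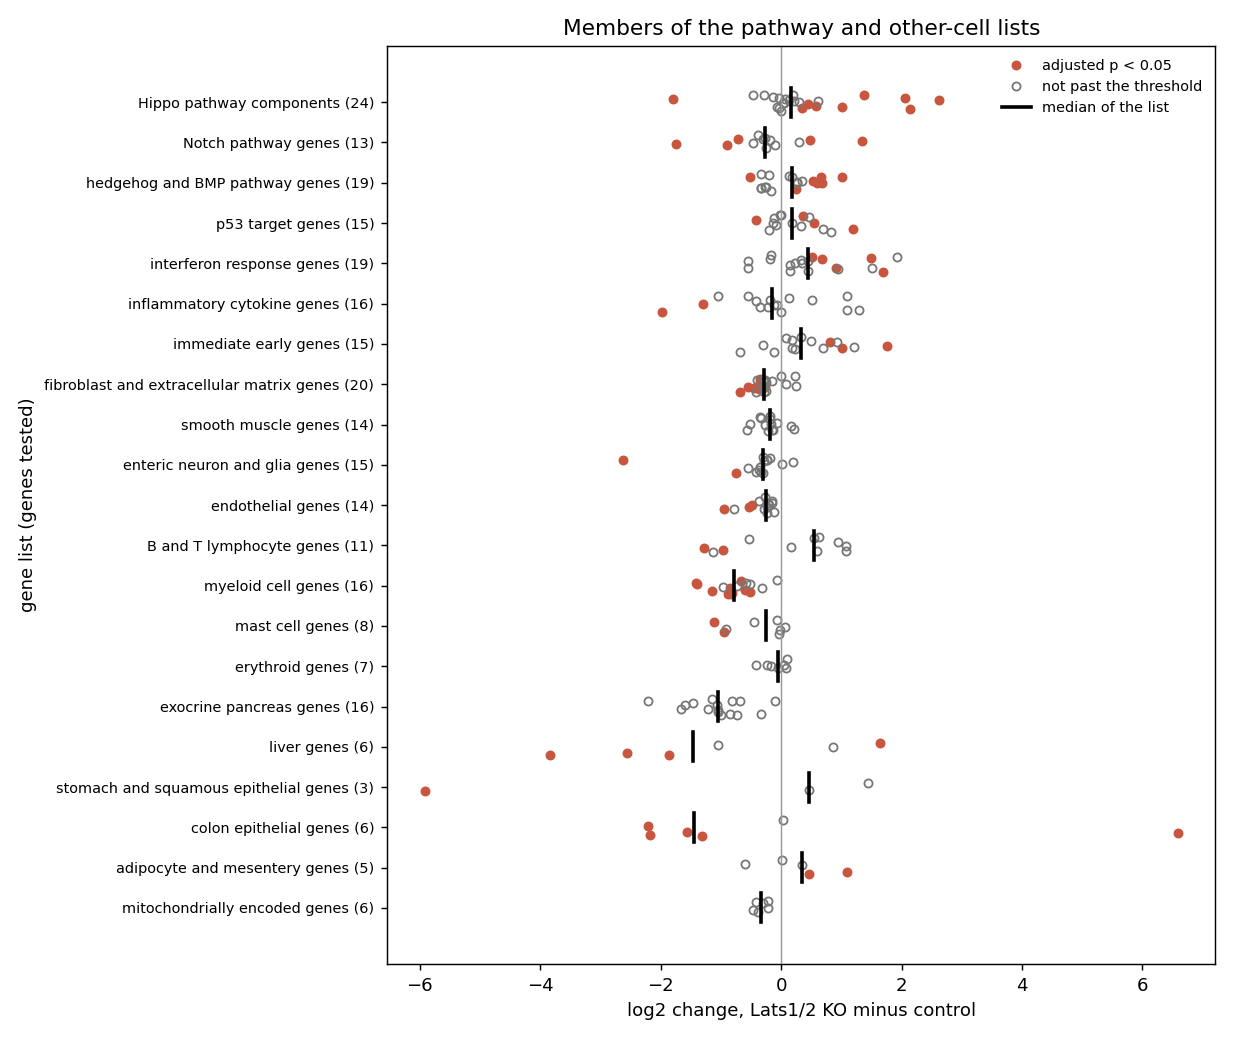
Log2 change (Lats1/2 KO minus control) of each tested member of 21 lists of other pathways, cell types and organs, with filled points past an adjusted p of 0.05, open points not past it, and a bar at the list median. The myeloid list has a median of -0.78 with every member below 0, and the fibroblast, endothelial, smooth muscle and neuron lists have medians of -0.29, -0.25, -0.18 and -0.30.

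The authors' deposited table gave an adjusted p for 16637 genes, of which 3827 were under 0.05, with 2129 higher and 1698 lower in the mutants. Of the authors' calls in the deposited table, 2054 were also higher and 1599 also lower in the limma fit, and 0 went the other way. A further 174 genes were called only in the authors' deposited table, 8 of them not tested here, and 855 were called only by limma. In the authors' deposited table Lats1 had a log2 fold change of -1.77 and Lats2 of -0.02. Log2 changes in the authors' deposited table and the limma fit correlated at r = 0.914 across tested genes, which are not independent replicates. The authors' deposited table gave Pgc a log2 fold change of -0.94, shrunken from the -5.92 of the limma fit.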

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

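The alternatives were listed before the data were examined, except limma with TMM scaling and with library size scaling, which were added after seeing the data. The list tests were not run under DESeq2. No paired analysis was possible because the columns of the deposited table carry no replicate numbers from the labels.

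Lats1 fell under every alternative run. Its log2 change was -1.88 to -1.70 with 1 library left out. The Lats2 log2 change was -0.14 to 0.08 with 1 library left out, turning sign without control replicate 2 or Lats1/2 KO replicate 2, and never passed. The count of genes was 4568, 4533 and 4511 with edgeR on recovered reads (TMM, DESeq2 size factors, library size only), 4514 with limma-voom and 3877 with DESeq2, of which 4454, 4450, 4372, 4426 and 3718 were among the 4508. It was 4456 with the stricter filter, 4458 with a pseudocount of 0.1, and 4526 and 4482 with TMM and library size scaling. Of the calls, 55.3% were higher in the knockouts, against 55.2% and 55.1% under these scalings. The median change of all tested genes was within 0.002 of 0 under each. With no filter 3040 genes passed, with the lower ones at 1318, as 29011 genes were then tested. Stricter thresholds by construction left fewer, with 1430 (694 higher, 736 lower) at 2-fold or more and 1751 (1024 higher, 727 lower) at an adjusted p under 0.01. With 1 library left out, assuming that the lone library varied like the other group, totals were 1869 to 3754, 908 to 2171 higher and 864 to 1612 lower. The fits without a knockout library gave the lowest totals.

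With an estimated correlation camera called 0 of the 11 and 0 of the 21 lists. On 2 residual degrees of freedom it could hardly call any, so this decides nothing. The camera p at 0.01 is still too small for lists whose genes are more correlated than that. Its adjusted p was 0.425 for the YAP, TAZ and TEAD, Wnt, fetal, goblet, Paneth, enteroendocrine and tuft lists, 0.485 for stem cells and 0.446 for the cell cycle. Fry called 3 of the 21 lists. The absorptive list passed with limma-voom (0.0348), no filter (0.0132) and fry (0.0271). With 1 library left out, 8 to 9 of the 11 and 6 to 11 of the 21 lists were called by camera. The Wnt list ranged from 0.0211 to 0.0591 and was lost without Lats1/2 KO replicate 2. Under the other alternatives run, the 9 called lists of the 11 kept their direction and call. The suckling-stage list turned upward with edgeR scaled by library size (0.676) and with fry (0.215).

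Other lists that turned direction were not called where they turned. For the stomach and squamous list of 3 genes the adjusted p was 0.679, 0.688 and 0.617 with edgeR in its 3 scalings, 0.524 with the stricter filter, 0.900 with fry, and 0.722 to 0.921 with 1 library left out. The B and T lymphocyte list turned with no filter (0.978) and without Lats1/2 KO replicate 1 (0.749 to 0.902 with 1 library left out). With 1 library left out, the erythroid list was at 0.187 to 0.598, the exocrine pancreas list at 1.18e-12 to 0.118, the smooth muscle list at 0.000171 to 0.961, and the log2 change of Slc4a1 at -0.48 to 0.01. The pancreas list was low in Lats1/2 KO replicate 1 and the smooth muscle list in replicate 2, and each turned without that library. For the other turns the cause was not tested. Of all comparisons of a named gene with an alternative, 36 lost a call, 21 gained one, 3 turned sign and 1127 did neither.

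Depth limited genes with few reads, since the median SE was 0.35 in the lowest of 5 groups of tested genes by level (means of 5.48 to 43.2 normalized counts) and 0.07 in the highest. The simulated fit found 22.4% of 1.5-fold changes with 200 genes changed, none of them at the level of the lowest group. That share does not carry over to the data, where 4508 genes passed and the cut on unadjusted p differs. A gene that did not pass here, above all one with few reads, can still differ by that much.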

Other observations

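Gene families, grouped by shared name after the data were seen, add groups outside the lists, and the single members named were chosen after their values were seen. Of 249 families with at least 8 tested members, 18 passed camera, and with an estimated correlation 0 did (adjusted p = 0.924 for each family named here). The latter test has 2 residual degrees of freedom and could hardly call any family. Translation initiation factors (Eif) rose in 23 of 52 and fell in 0, with a median log2 change of 0.26 and an adjusted p of 1.86e-05. Eif2s2 and Eif1a rose by 0.88 and 0.70 on the log2 scale. Nucleoporins (Nup) rose in 12 of 21, DEAD-box helicases (Ddx) in 11 of 34 and nucleolar proteins (Nop) in 7 of 8, each with 0 falling. Keratins rose in 8 of 14 with 0 falling and a median of 1.09. Krt8 and Krt18, the keratin pair of simple epithelia, went from 15590.1 ± 19.7 to 39441 ± 2110.4 and from 8640 ± 137 to 24786 ± 2031 normalized counts (SD, n = 2 each). Chemokines (Ccl) fell in 6 of 10 with 0 rising, among them Ccl9 (-3.75) and Ccl28 (-2.35), and collagens in 8 of 41 with 0 rising.

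Other single genes, all chosen after their values were seen, stood out. Wnt3, a Wnt ligand made by Paneth cells, fell from 62.2 ± 8.71 to 2.75 ± 1.34 normalized counts (SD, n = 2 each), and Sfrp5, a secreted Wnt inhibitor, from 202 ± 94.0 to 9.14 ± 0.153. Psca, a surface protein of stomach and bladder epithelium, had 1 and 4 reads in the control libraries and 201 and 400 in the knockouts. Fgf15, an ileal hormone, had 0 reads in both control libraries and 26 and 52 in the knockouts. Bex3 rose from 756 ± 98.3 to 9799 ± 201, and Vnn1, a pantetheinase, from 543 ± 76.4 to 7059 ± 69.5.

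The tests of Lats2, of the shared fall of stromal markers, with the adipocyte and lymphocyte lists beside it, and of the further fall of myeloid markers were chosen after the results were seen. The scalings were added after seeing the data. The bounds of the other tests were written before those tests were run, but after the falls they address were seen. There were 4 genes of the pyloric gland mucosa and stomach, put together after their values were seen, that fell, namely Muc6 (1016 and 323 normalized counts in the controls, 10.2 and 9.94 in the knockouts), Gkn3, A4gnt (210 and 88 reads against 1 and 2) and Pgc. The lists cannot speak for stomach genes at large, as 3 of 15 stomach and squamous genes and 2 of 10 pyloric and gastric genes could be tested. Of these only Pgc, itself among the 4, fell past the threshold by limma. Ctse had a log2 change of -1.02 (adjusted p = 0.167), while Gata3 (0.52) and Atp4a (1.45) had few reads. Psca rose. For less proximal gut in the knockout samples, the fall set before that test was run was a median of 1 or more on the log2 scale in proximal epithelial genes. Their median was -0.24 ± 0.34 (SE across 8 genes, with Pdx1 at 0.07). The median less 2 SE was -0.92, which cleared that bound only narrowly, with an SE that takes the genes as independent. A smaller loss was not tested, so less proximal gut stays open. Cybrd1, Onecut3 and Tmprss15 did fall, by 1.27 to 1.80, and the rise of Fgf15 goes with less proximal gut, while 0 of 12 listed distal genes could be tested. A missing piece of pylorus stays open, since 2 of 10 pyloric and gastric genes could be tested (median -0.25) and the control libraries differed severalfold. The whole-tissue libraries do not show which cells or which part of the gut expressed these 4 genes. An effect of the genotype on those cells, wherever they lie, cannot be told apart from a missing piece of pylorus.

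Lats2 kept its control level while Lats1 fell. Too few Lats2 reads to show a fall like that of Lats1 are excluded. The lower 95% bound of its log2 change (-0.34) lies above the upper bound for Lats1 (-1.55). A smaller fall of Lats2, down to that lower bound, is not excluded. A swapped library is also argued against, as the lowest control Lats1 value was 3.08 times the highest in the knockouts. Lats2 reads may come from cells without Cre or from the part of the gene left after deletion, and with 29% of the control Lats1 left and no reads per exon analysed here, this cannot be told apart from incomplete deletion or higher transcription of Lats2.

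Stromal markers were lower on balance, with a median of -0.27 ± 0.06 (SE across genes) over 63 genes, of which 56 were negative, 12 fell and 0 rose. An effect of the authors' scaling cannot be told apart from it, since the other 2 scalings moved this median by under 0.002 and so tested nothing. A lower share of all non-epithelial cells in the knockout samples cannot be told apart for the stromal part either. The medians of the 4 stromal lists differed by at most 1.08 standard errors, but by 2.38 in Lats1/2 KO replicate 1 alone, where smooth muscle genes were at -0.001 and endothelial genes at -0.26. The adipocyte and lymphocyte lists, with medians of 0.34 and 0.54, lay 1.73 and 2.33 standard errors above the stromal median, though 0 lymphocyte genes rose and 2 fell. An equal loss goes less well with myeloid markers, whose median of -0.78 lay -3.99 standard errors from the stromal one. These standard errors are across genes, which are not independent, and hold no spread between samples. The myeloid mean was -0.86 in Lats1/2 KO replicate 1, where the lowest stromal mean was -0.34. In replicate 2 they were -0.68 and -0.56. The control libraries had myeloid means of 0.15 and -0.15, so the difference in replicate 2 lies within their spread. An equal loss as the whole account goes less well with replicate 1 alone, and it stays open. A myeloid change with the genotype stays open and was not tested here.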
